A study of Homo sapiens with 2 samples.

How the data were processed

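SRC-2 (NCOA2), a coactivator of the p160 family that is brought to DNA by nuclear receptors and other transcription factors and does not read DNA sequence itself, was immunoprecipitated with bound chromatin from human endometrial stromal cells and sequenced (ChIP-seq). The cells had been exposed to a decidualizing mixture of 10 nM estradiol, 100 nM medroxyprogesterone acetate (a synthetic progestin) and 1 mM cAMP in medium with 2% stripped serum. The series holds 1 SRC-2 ChIP library and 1 input library, which is DNA from the same kind of sonicated nuclei without an antibody. Per the labels' protocols, both were built from fragments selected at 200 to 300 bp and amplified for 18 cycles.

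The values used come from the peak list of the ChIP library. Per the submitters' processing notes, the reads were handled with BWA and MACS 1.3.7.1 on GRCh37.p2; those notes give the names without role or order, and the thresholds, filters and number of reads are not given in the sources used here. Per the file headers, the deposited list has 2 sections, a track of points and a track of intervals. The points are called summits here, because each point lay inside the interval of the same rank. Each summit carries a deposited score, a whole number that is called its height here; the file does not say what 1 unit of it counts, so heights are compared only within this list. It gives no background level from the input and no p-value or FDR per interval. No file of the input library was used here, so the authors' background could not be weighed.

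Of the summits, 69.2% lay at multiples of 32 bp and 94.6% at multiples of 16 bp, so positions follow a grid and are not resolved to the base. Interval starts are printed with 1 added to the deposited start, as for a BED file, and summits are printed as deposited. Intervals on chromosomes 1 to 22 and X were analysed. The sequencing depth and the unit of the heights are unknown, so the counting error of a height could not be computed. With 1 library per group, no difference has a replicate check. Intervals printed for shares and densities are exact 95% binomial (Clopper-Pearson) or Poisson intervals and cover counting error only. They treat summits as independent, which summits lying close together are not, so they are likely too narrow.

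The analysis was done in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. Summit density was the number of summits on a chromosome divided by the distance from its first to its last summit. Spacing was described by the share of summits with another within 50 kb and set beside 1000 local shifts, in which each summit was moved at random by up to 1 Mb either way, and beside 1000 placements at random between the first and last summit of the same chromosome. Clusters were runs of at least 4 summits with at most 100 kb between neighbours. Heights of summits with and without a close neighbour were set beside 10000 random reassignments of the same heights. The placements and reassignments describe this list and are not tests between conditions. On simulated lists of 1831 summits placed evenly at random along each chromosome, 0 of 10 had a share within 50 kb above all of 100 local shifts. With 10% of summits given a partner 5 to 50 kb away, 10 of 10 did, at a mean share of 24.6%. The simulated lists lack the uneven density of the deposited one. They therefore do not show how the local shifts behave under such unevenness or with a weaker excess.

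The planned comparisons with promoters, sequence motifs and 13 gene lists fixed before the data were examined needed a genome and annotation of GRCh37; the gene table at hand is of GRCh38.p14, so it was not used and these comparisons were not made. The rule for named genes, fixed at the same time, names none without such an annotation. It also takes the 15 highest summits, which are reported by position. The alternatives were the summits at or above the median height, merging of intervals within 1 kb, other distances and shifts, and leaving out the 15 highest summits, the summits beside the longest summit-free stretch of each chromosome, or chromosome X. The description of the number, width and height of the intervals was planned; the comparisons of spacing, clusters, chromosomes, and heights with and without a close neighbour were chosen after the data were seen.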

Results

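The series asks where SRC-2 sits on the genome of endometrial stromal cells under a decidualizing stimulus. Decidualization is the change of these fibroblast-like cells into the secretory cells that support an implanting embryo, and it is driven by progesterone and cAMP. The series holds 1 library of SRC-2 ChIP-seq and 1 input library, so the data describe a single set of called regions and hold no comparison with untreated cells. Positions are on GRCh37 per the submitters' processing notes, and the gene, exon or intron at each position was not annotated here.

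SRC-2 was called in 1831 intervals on chromosomes 1 to 22 and X, which together covered 1.27 Mb. Most intervals were short. Their median width was 661 bp, with quartiles of 529 and 810 bp and a full range of 270 to 4844 bp. The summit lay near the middle of its interval, at a median of 46.6% of the width from the start, with quartiles of 37.1% and 56.6%.

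Most of the summits were low. The median height was 10, with quartiles of 8 and 13, and 122 summits (6.66%) reached 20. A height of 30 was reached by 24 summits (1.31%) and a height of 50 by 5, and the highest stood at 86. Higher summits lay in wider intervals. The median width was 564 bp for the 414 intervals of height 7 or less, 743 bp for the 389 intervals of height 13 to 19 and 810 bp for the 122 intervals of height 20 or more. Across intervals, which are not independent replicates, Spearman's rho between height and width was 0.34, and it was 0.33 without the 15 highest summits.

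**Figure D1:**
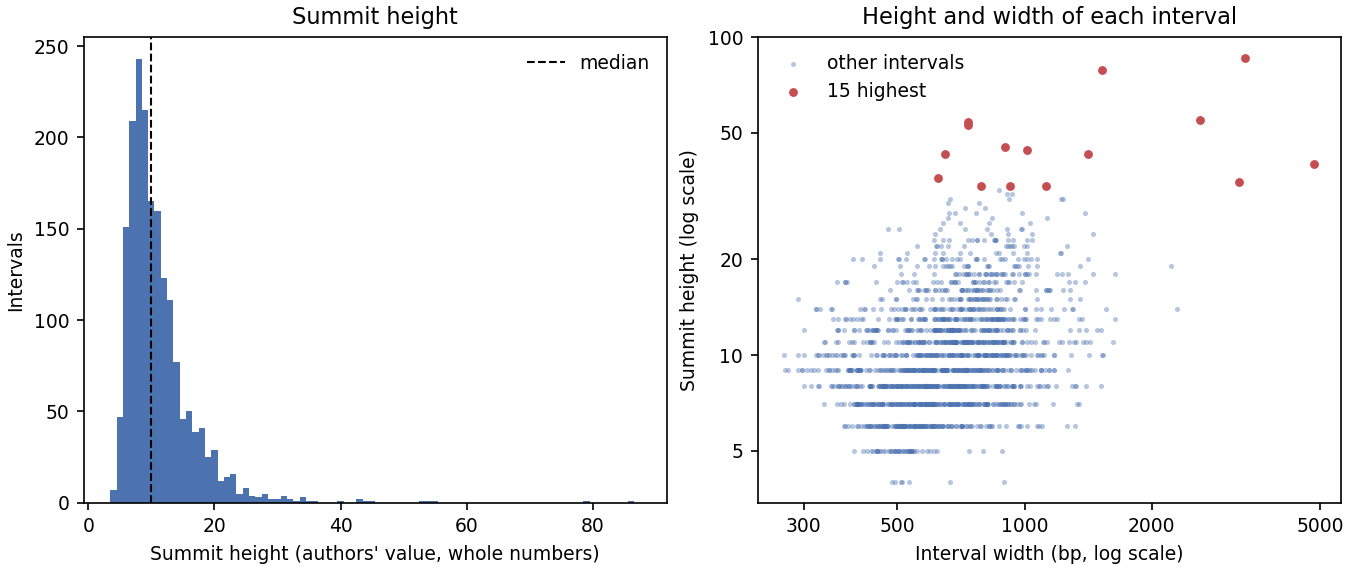
Left, number of intervals at each summit height (the authors' whole-number value), with the median of 10 as a dashed line. Right, summit height against interval width in bp on log axes for each of the 1831 intervals, with the 15 highest summits in red; some of these lie in intervals far wider than the median of 661 bp.

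The highest summit, 86, was at 58,778,960 on chromosome 6, in an interval of 3320 bp from 58,776,109 to 58,779,428. The next was 79 at 121,484,928 on chromosome 1, in an interval of 1523 bp. Heights of 55, 54 and 53 followed at 9,825,680 on chromosome 21, at 156,186,432 on chromosome 1 and at 61,969,344 on chromosome 7. A summit of 45 lay at 95,168,192 on chromosome 1. Chromosome 10 held a pair of high summits, 44 at 42,379,904 and 43 at 42,396,864. Chromosome 8 held another pair in adjoining intervals, 43 at 43,095,904 and 35 at 43,095,072. The widest interval of the whole list, 4844 bp from 18,515,633 to 18,520,476 on chromosome 18, had a height of 40. The remaining members of the 15 highest were 36 at 4,438,352 on chromosome 20, and 34 each at 76,483,776 on chromosome 11, 15,782,208 on chromosome 12 and 47,497,792 on chromosome 7. Of these 15 summits, 6 lay in intervals over 2 times the median width, against 2 of the 100 next highest, or 3 of 107 when all summits tied at a height of 20 are counted. Of the 15, 5 lay within 1 Mb of one of the 2 longest summit-free stretches of their chromosome. Which of them lie in repeats was not determined here. Reads piled up on repeated sequence are a candidate explanation for part of them, so their order is not an order of SRC-2 binding.

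Called intervals were found on every autosome and were sparse on chromosome X. Pooled over the 22 autosomes, there were 0.67 summits per Mb between the first and last summit of a chromosome. Chromosome 22 had the highest density, at 0.87 per Mb (95% Poisson interval 0.58 to 1.26), and chromosome 17 was at 0.87 (0.67 to 1.10). Chromosome 9 had the lowest of the autosomes, at 0.47 (0.36 to 0.60), and its span includes a stretch with no summit in its middle. Chromosome X carried 22 summits, or 0.15 per Mb (0.09 to 0.23). That was 0.22 times the pooled autosomal density, with an exact 95% interval of 0.14 to 0.34. The median height per chromosome ran only from 9 to 12, and chromosome X was at 9.5. Its intervals were narrower, with a median of 475.5 bp. How much of each chromosome could be called is unknown from the list, so the densities are not corrected for it.

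**Figure D2:**
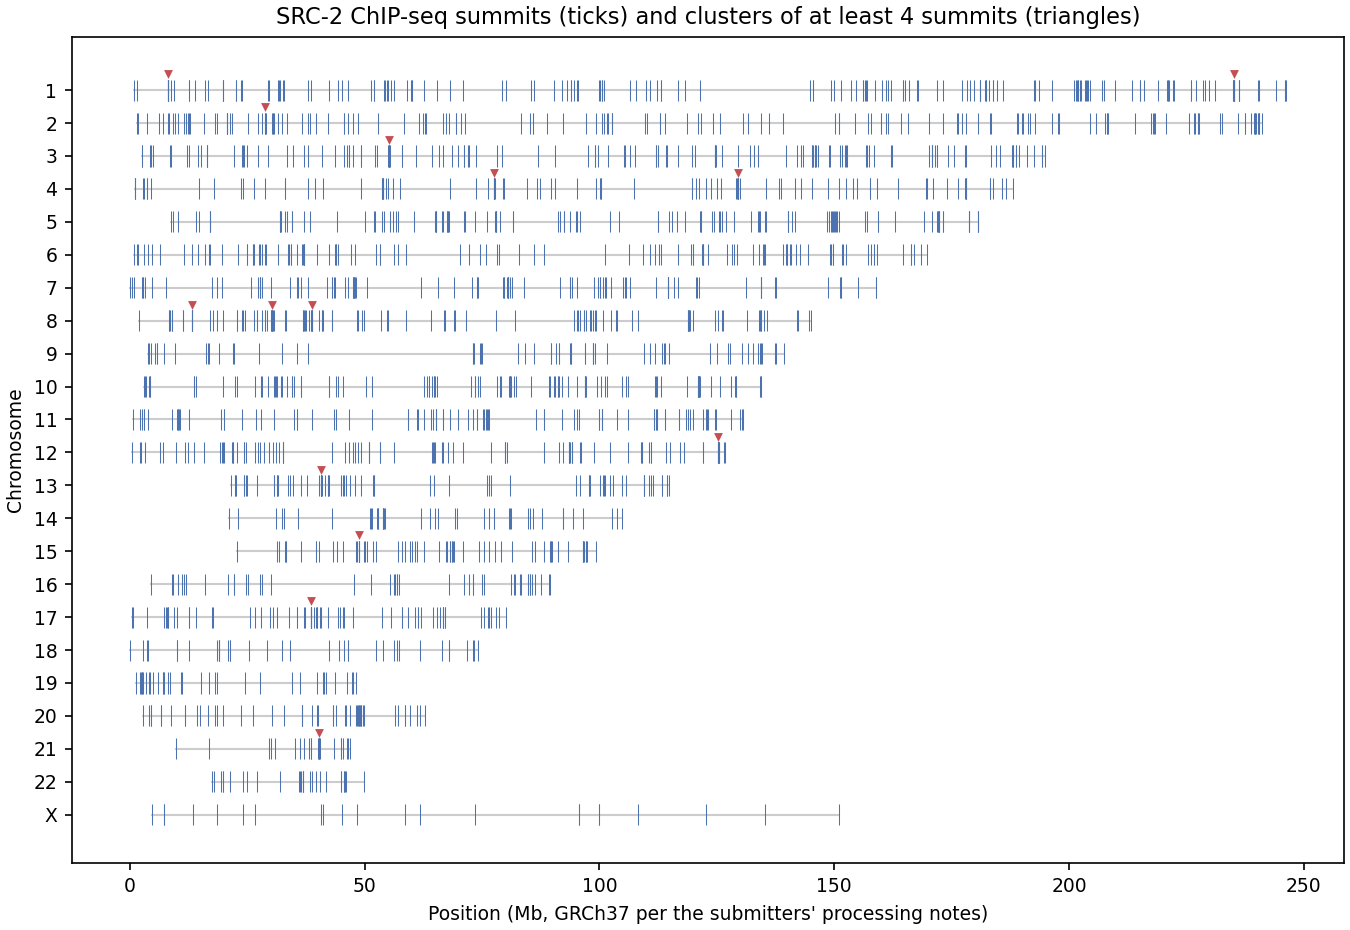
Position in Mb (horizontal) of every summit on chromosomes 1 to 22 and X (rows), drawn as ticks on a grey line from the first to the last summit; red triangles mark the 14 clusters of at least 4 summits. Chromosome X carries 22 summits, or 0.15 per Mb, against 0.67 per Mb over the autosomes.

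SRC-2 summits lay close to one another more often than local chance. Of the 1831 summits, 413 (22.6%, exact 95% interval 20.7% to 24.5%) had another within 50 kb. A close neighbour is mutual, so these summits are not independent and the interval is too narrow. When each summit was moved at random by up to 1 Mb, the share averaged 9.77% and its highest value in 1000 such shifts was 12.6%. Without the 15 highest summits the share was 22.4%, against a mean of 9.76% in the shifts. The median distance to the nearest summit was 268 kb, against a mean of 383 kb in the shifts. The excess was strongest at short range. Neighbouring summits 1 to 5 kb apart numbered 39 against a mean of 7.64 in the shifts, and those 10 to 20 kb apart numbered 54 against 18.7. At 20 to 50 kb the numbers were 92 and 54.9, and the highest of the shifts was 79. At 50 to 100 kb the 102 observed pairs fell inside the range of the shifts, which reached 114. Farther apart there were fewer pairs than in any shift. At 200 to 500 kb they numbered 269 against a lowest of 301, and at 500 to 1000 kb 286 against 296.

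**Figure D3:**
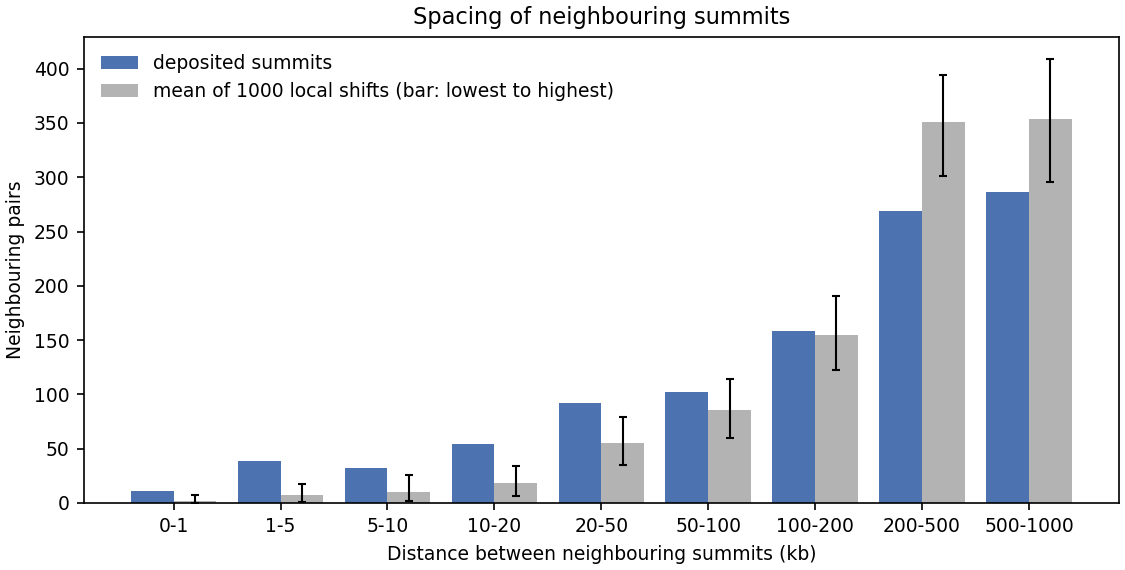
Number of neighbouring pairs of summits (vertical) by the distance between them in kb (horizontal), for the deposited summits (blue) and as the mean of 1000 local shifts of up to 1 Mb (grey, with bars from the lowest to the highest shift). The deposited summits lie above the highest shift in every class up to 50 kb, for example 54 pairs against a mean of 18.7 at 10 to 20 kb. They lie below the lowest shift in the classes from 200 to 1000 kb.

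In all, 14 clusters of at least 4 summits, with at most 100 kb between neighbours, held 64 summits on 10 chromosomes. The local shifts gave a mean of 2.97 such clusters and at most 8. The number of clusters depends on the settings: it was 6 with at most 50 kb between neighbours, against a mean of 0.46 and at most 4 in the shifts, and 6 among the 959 summits of height 10 or more, against a mean of 0.41 and at most 4. None of the 15 highest summits was in the 14 clusters, which held 64 of the 1831 summits, so few or none would be there by share alone. Clusters of at least 3 summits numbered 61, against a mean of 19.6 and a highest of 34 in the shifts.

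The largest cluster in the local shifts held a mean of 4.46 summits and at most 8, so a size of 6 lies within their range. The 3 largest clusters of the deposited list held 6 summits each. The first ran over 98.4 kb of chromosome 1, from 8,099,644 to 8,198,064, and its summits had heights of 7 to 25, the highest at 8,194,160. The second covered 251 kb of chromosome 8, from 30,175,269 to 30,426,494, with heights of 6 to 20. The most compact was on chromosome 17, from 38,641,951 to 38,708,703, where 6 summits of heights 9 to 18 lay within 66.8 kb. Clusters of 5 summits lay on chromosome 1 from 235,056,837 to 235,184,433, with heights of 8 to 15, and on chromosome 4 from 77,484,281 to 77,660,149, with heights of 8 to 16.

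The other 9 clusters had 4 summits each. The highest summits among them were 32 at 28,849,920 on chromosome 2, in a cluster from 28,847,903 to 28,939,741, 24 at 129,581,632 on chromosome 4, in a cluster from 129,438,965 to 129,629,441 whose median height was 21, and 23 at 13,215,040 on chromosome 8, in a cluster from 13,214,526 to 13,304,102. A cluster on chromosome 13, from 40,710,767 to 40,811,008, reached 22 at 40,795,616. One on chromosome 3, from 55,162,192 to 55,223,858, had a median height of 16. A further cluster on chromosome 8, from 38,708,265 to 38,796,562, reached 16. The remaining ones were on chromosome 12 from 125,166,378 to 125,260,922, on chromosome 15 from 48,732,083 to 48,875,125 and on chromosome 21 from 40,292,940 to 40,450,094, with highest summits of 16, 16 and 15.

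**Figure D4:**
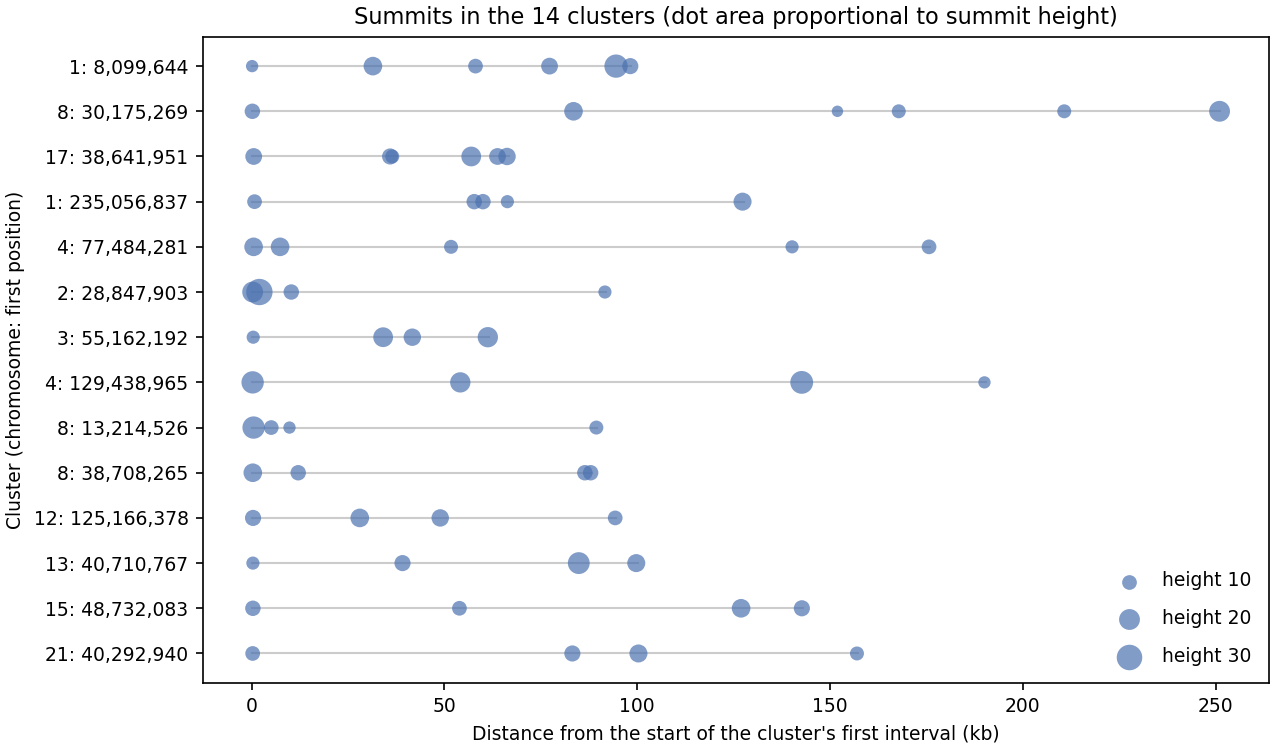
Each row is 1 of the 14 clusters, named by chromosome and first position; dots mark its summits by distance in kb from the start of the first interval, with dot area proportional to summit height. The clusters on chromosomes 1, 8 and 17 at the top hold 6 summits each, and the one on chromosome 17 spans 66.8 kb.

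Summits with a close neighbour were slightly higher than those without. The 413 summits with another within 50 kb had a median height of 11 (quartiles 8 and 14) and a mean of 12.2. The other 1418 had a median of 9 (quartiles 8 and 13) and a mean of 10.9. The difference of the means, 1.36, lay above the upper 2.5% limit of 0.65 in 10000 random reassignments of the heights. The reassignments treat summits as independent, which close neighbours are not, so that limit may be too narrow. Among the 959 summits of height 10 or more the difference was 0.74, inside their limit of 1.02. That set is selected on height itself, and close neighbours were counted only within it. Whether either of these lowered the difference was not tested. The intervals with a close neighbour were also wider, with a median of 709 bp against 645 bp.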

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

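The tests of the highest summits were chosen after the result was seen; those of summit spacing were set after a first look at the list and before their values were computed.

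The list holds 1 interval on the mitochondrial genome, which the comparisons above do not use. It runs from position 1 to 4490 and its summit at 3632 has a height of 183, which is 2.13 times the highest summit on any chromosome used above and 18.3 times the median. It was singled out because it is a called signal outside the main measurement. No level of the input was at hand for it, so its height was set against no background. The ratios compare deposited heights only and do not show that more SRC-2 was bound there.

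The top of the list rises to 86, 79 and 55, while the 15 highest as a set run on into the rest, from 34 to the next height of 33. Of the 15 highest, 5 lay within 1 Mb of one of the 2 longest summit-free stretches of their chromosome, where 8.74% of all summits lie; random sets of 15 summits had a mean of 1.32 there and an upper 2.5% limit of 4, and the highest of 10000 sets had 7. Of the same 15, 6 (40%, exact 95% interval 16.3% to 67.7%) lay in intervals over 2 times the median width, against 2 of the 100 next highest (2%, 0.24% to 7.04%), or 3 of 107 (2.80%, 0.58% to 7.98%) when all summits tied at a height of 20 are counted. The adjoining pair on chromosome 8 makes up 2 of these 6, so they are not independent and the interval is likely too narrow. Width also rose with height across the list, with a Spearman's rho of 0.34, and the count does not separate that from repeats. Both the 5 and the 6 go with reads piled up on repeated sequence as a candidate explanation for part of these summits. The stretches are only free of summits in this list and were not shown to be sequence that could not be called. Of the 15, 7 were neither wide nor beside such a stretch, but this cannot clear them of that explanation. Only the 2 longest stretches of each chromosome were counted. The pair of heights 44 and 43 on chromosome 10, among these 7, follows a further long summit-free stretch that was not counted. The design holds no second condition, so no biological explanation was tested, and values of the input library were not used here.

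The short spacing of summits was weighed in the same way. Intervals split from 1 region a few kb wide would add pairs under a few kb. Yet 179 neighbouring pairs lay 5 to 50 kb apart, against a mean of 83.0 and a highest of 111 in the local shifts. Splitting of regions that narrow is therefore not the whole cause. It stays open for the 11 pairs under 1 kb and the 39 pairs at 1 to 5 kb. The count cannot weigh splitting of broader regions, which would also add pairs at 5 to 50 kb. The share within 50 kb averaged 6.53% in placements anywhere on the chromosome and 9.77% in the local shifts, which keep uneven density over megabases. That gap cannot be credited to such unevenness alone, because close groups spread out by the shifts also raise the shifted share. On the evenly placed simulated lists the shifted share averaged 6.50%, and 7.35% with 10% of summits given a partner. The observed 22.6% against the highest shift of 12.6% is the comparison already given in the results and not a further test. Leaving out the summits beside the longest summit-free stretch of each chromosome gave 22.5%, against a highest of 12.6% in their own shifts. Unevenness at a finer scale, such as the placement of genes or of open chromatin, stays open and may account for the excess: with shifts of up to 250 kb the observed share was still 1.61 times the mean of the shifts. No biological explanation was tested, since the design holds 1 condition.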

How the results depend on the processing

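The alternatives to the count, width and height of the intervals were fixed before the data were examined, and all others were added after seeing them. No paired analysis was possible because each group has 1 library, and no replicate could be left out. The planned promoter, motif and gene list results, the score at promoters, and all their alternatives were not run for want of a GRCh37 genome and annotation, and the FDR threshold was not run because the list gives no FDR. Of 26 alternative values, 15 stayed within the spread set for them or on the same side of the limit of the random sets, 10 moved, 1 fell inside that limit and 0 reversed. Most of the 15 came from settings that change few summits, such as merging within 1 kb, which left 1814 intervals, or leaving out the 15 highest. Those values could hardly move. Taking only the summits at or above the median height of 10 left 959 intervals by construction, with 6 clusters of at least 4 summits in place of 14 and a share within 50 kb that was 3.35 times its local shifts in place of 2.31. That ratio was 3.44 at a distance of 20 kb, 1.73 at 100 kb, 1.61 with shifts of up to 250 kb and 3.45 against placement anywhere on the chromosome; in each of these settings the observed share was above the highest of the 1000 placements. A gap of 50 kb in place of 100 kb left 6 clusters of at least 4. The ratio was 2.19 with intervals within 1 kb merged, 2.30 without the 15 highest summits, 2.32 without the summits beside the longest summit-free stretches and 2.31 without chromosome X. Among those 959 summits, a set selected on height itself, the height difference between summits with and without a close neighbour was 0.74. That lay inside the upper 2.5% limit of the random sets. In the other 4 settings the difference (1.08 to 2.07) lay above that limit. Such limits treat summits as independent, so they may be too narrow. Chromosome X stayed at 0.23 to 0.24 times the autosomal density in its 3 alternatives. The unknown depth limits all of these: a region missing from the list may have been below what this library could call.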

Other observations

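At the scale of megabases, the windows of 1 Mb with the most summits held 8 each. They lay on chromosome 8 from 30,072,990 to 30,636,180, on chromosome 17 from 38,641,951 to 39,572,819 and on chromosome 20 from 48,391,825 to 49,306,993. The one on chromosome 20 had a median height of 14.5 against 10 over the whole list, and it contained none of the 14 clusters described above. Another 8 windows held 7 summits each. The most compact of them was on chromosome 12, where 7 summits lay within 246 kb from 125,166,378 to 125,412,768, and the next on chromosome 1, within 327 kb from 234,857,045 to 235,184,433. One on chromosome 10, from 121,006,564 to 121,425,765, overlapped none of the clusters. The one on chromosome 7, from 47,497,559 to 48,180,213, held the summit of height 34 listed among the 15 highest. When summits were placed at random between the first and last summit of each chromosome, the fullest window held a median of 6 summits over 1000 placements, and 5 of the placements had a window with 8, which was the most seen. Such placements do not keep the uneven density over megabases, so they cannot tell these windows from that unevenness. These windows were chosen after the data were seen.

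Several wide intervals were not among the highest. On chromosome 17, intervals of 2298 bp from 8,022,076 to 8,024,373 and of 2217 bp from 8,089,256 to 8,091,472 had heights of 14 and 19, and they were the widest intervals of the list outside the 15 highest summits.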
